A study of Homo sapiens with 16 samples.

How the data were processed

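The samples were 16 co-cultures of a human cancer line with mouse cells, hybridised to a human 6-sample BeadChip of version 2. Per the labels' protocols, total RNA of the mixed culture was extracted and converted to biotin-labelled cRNA, and probe signals were exported with BeadStudio, whose version is not given in the sources used here. Groups were taken from the sample titles, which name the line, the partner and the replicate number, and from the source names. A further label field names MDA-MB-231 with astrocytes for all 16 samples; it contradicts the titles and source names of 12 and was not used. The mouse arrays hybridised with the same kind of RNA and any cultures of a single cell type were not analysed here.

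The deposited raw table holds linear intensity values, 1 per probe and array, for 48687 probes, not normalised between arrays and without detection p-values, control probes or slide positions. The authors' processed table holds log2 values with 3 decimals. Set against the raw table, it equalled the quantile-normalised log2 of the raw intensity, with no background correction and no centring of genes, to within 0.0026, while the next nearest match of any probe lay 0.0556 or more away; each of its columns had a median of 6.151. Its scale, centring and direction are therefore known. The normalisation is read from these values and is not stated in the labels. Probes were named through the match between both tables and the platform annotation: 23675 probes had 1 gene symbol, 35 several and 24977 none in the annotation used here. Symbols were looked up by gene number for 23639 probes in a RefSeq gene table of assembly GRCh38.p14, which updated 0. Probes with several symbols were named as none.

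Raw intensities were corrected for background with normexp (offset 50), quantile normalised and put on the log2 scale with limma 3.58.1 in R 4.3.3. The design fixed before the data were examined used detection p-values for the background and for a filter where the files gave them; they did not, so its stated branch without detection p-values was used and no probe was filtered out. For a gene with several probes the brightest over all 16 arrays was kept, and unnamed probes were kept on their own, giving 43785 features with 18773 named genes. Of the called genes with other probes on the array, 36 of 276 in MDA-MB-231 and 17 of 147 in PC14 had another probe called the same way, and 0 and 1 had another called the opposite way. No probe can be called above background without detection p-values. Group means under log2 6.5 were read as near the floor. No depth applies to arrays, and their number limits the precision.

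All 16 arrays entered a single limma fit of 4 group means (lmFit and eBayes), with Benjamini-Hochberg adjustment over all 43785 features and a threshold of 0.05. The contrasts were astrocyte minus fibroblast co-culture within each line, the difference of these 2 contrasts, and PC14 minus MDA-MB-231 averaged over the partners. A gene counted as shared when it passed in both lines in the same direction. Lists of genes, 33 in all with 704 of 755 entries measured, were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, with camera at an estimated correlation and with fry. Of the lists that passed, 11 of 15 held with an estimated correlation in MDA-MB-231, 6 of 10 in PC14 and 2 of 6 for the difference between lines.

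Genes to be named were fixed by rule at the same time. They were the 8 largest rises and 8 largest falls of each partner comparison among called genes whose array values did not overlap, up to 4 members of each list with the smallest adjusted p, the 8 and 8 largest shared changes, the 5 largest differences between lines each way, the 8 largest line differences each way, and BCL2L1, GSTA5 and TWIST1. Genes without a usable symbol, XIST and Y-linked genes were left out of the rule. PDIA6 was named outside it, after its values were seen, and 1 gene that the rule picked is not reported. The lists covered reported survival genes, apoptosis, glutathione S-transferases, NRF2, drug transporters, EMT, epithelial genes, interferon, antigen presentation, NF-kB, JAK-STAT3, cell cycle, cholesterol, hypoxia, TGF-beta and YAP, the unfolded protein and ATF4 responses, immediate early genes, p53, heat shock, metallothioneins, Notch, endothelin and gap junctions, proteases, serpins, neural genes, ribosomal proteins, oxidative phosphorylation and markers of 5 cell types.

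The pairing of replicate numbers was checked as the correlation of same-numbered arrays' deviations from their group means. Over features above the median it was 0.16, 0.16, 0.11 and 0.47 for numbers 1 to 4 in MDA-MB-231 and 0.21, 0.31, 0.55 and 0.43 in PC14. Over all features the lowest was 0.08, for number 3 in MDA-MB-231. Each same-number correlation over the brighter features was 0.11 or more, so the numbers were taken to pair arrays. For 3 of the 8, however, a different number correlated more, and the labels do not say what a number marks. The main fit was fixed beforehand without a block, so its errors and adjusted p leave this pairing out. Counts with the number as a block are given beside the main ones. The arrays numbered 4 deviated together across groups, with correlations of 0.35 to 0.53.

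The fit was tested on simulated data for the MDA-MB-231 comparison over 43785 features. It recovered 39 of 50 genes changed by 0.5 on the log2 scale, 47 of 50 changed by 1, 50 of 50 changed by 2 and 48 of 48 changed by 3, with 7 false among 191 calls. The changed genes were drawn only from those with a mean above log2 8. The simulated noise was independent between arrays, and the lines did not differ. These rates therefore do not cover dimmer genes or the correlation of same-numbered arrays. Alternatives were no background correction (with signals floored at 1), 75th percentile scaling, cyclic loess, the authors' processed values, the mean of all probes, the replicate number as a block within each line, array weights, a variance trend with a robust prior, only the arrays compared, and each array left out in turn. After the data had been seen, 4 were added. These were dim features left out, the 4 arrays numbered 4 left out, a block shared by both lines, and adjustment over named genes alone. For the gene lists, the alternatives fixed beforehand were cyclic loess, the authors' processed values, the block within each line, the estimated correlation and fry. The other alternatives were not fixed beforehand for the lists. Other scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.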

Results

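Human cancer cells were grown together with mouse cells, and total RNA of each mixed culture was hybridised to a human expression BeadChip, so mouse RNA was present on every array. The human cells were MDA-MB-231, an established breast cancer line, or PC14, an established lung cancer line. The partner was either mouse astrocytes, the star-shaped support cells of the brain, or NIH 3T3, an established mouse fibroblast line. The 16 arrays formed 4 groups of 4, 1 group for each line and partner. The median raw intensity ran from 63.5 to 82.1, and the array numbered 4 was the brightest of its group in all 4 groups. Pearson correlations across the features brighter than the median feature were 0.9925 to 0.9976 between arrays of a group. They were 0.9867 to 0.9954 between the partners of a line, and 0.9104 to 0.9219 between the lines. Values below are log2 intensities as mean ± SD with n = 4, and changes are log2 differences of astrocyte minus fibroblast co-culture ± SE. The labels do not state that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Groups with a mean under log2 6.5 were read as near the floor; a fold against 1 such group can understate the change, and a change between 2 is poorly measured.

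The first comparison asked which genes MDA-MB-231 co-cultures expressed differently beside astrocytes than beside fibroblasts. GPM6B, a membrane glycoprotein of neurons and glia, was 49.6-fold higher beside astrocytes, at 11.79 ± 0.15 against 6.16 ± 0.05 (SD, n = 4; log2 change 5.63 ± 0.08). GSTA5, an alpha-class glutathione S-transferase, was 9.86-fold higher, at 9.77 ± 0.25 against 6.46 ± 0.08 (adjusted p = 6.1e-18). DLK1, a transmembrane protein related to the Notch ligands, was 70.1-fold lower, at 6.19 ± 0.07 against 12.32 ± 0.10, a log2 change of -6.13 ± 0.08. HERPUD1, which serves the degradation of misfolded proteins at the endoplasmic reticulum, was 7.64-fold lower, at 8.79 ± 0.07 against 11.72 ± 0.41 (adjusted p = 4.8e-14). Other large rises were those of EFNB2, a ligand of Eph receptors (5.43-fold), the transcription factor TCF4 (5.22-fold), NREP (5.10-fold), the sugar epimerase RENBP (4.07-fold), the microtubule regulator STMN2 (3.95-fold) and the cardiac actin gene ACTC1 (3.49-fold). Other large falls were those of RAB42, a small GTPase (7.31-fold), the homeobox gene MEIS1 (6.58-fold), the matrix proteoglycan gene DCN (5.59-fold), DDIT4, an inhibitor of mTORC1 (4.79-fold), DDIT3, which encodes the stress factor CHOP (4.66-fold), and FEZ1, a gene of axon growth (4.55-fold). That the 4 astrocyte and 4 fibroblast values did not overlap was a condition for naming these genes.

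In all, limma called 1232 of 18773 named genes in MDA-MB-231, 536 higher and 696 lower beside astrocytes, with a median absolute log2 change of 0.39. Of these, 34 were over 2-fold higher and 48 over 2-fold lower, and the array values of the groups did not overlap for 1107. With the replicate number as a block the count was 1918, of which 898 were higher and 1020 lower. With each array scaled to its 75th percentile it was 591, 254 higher and 337 lower.

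**Figure D1:**
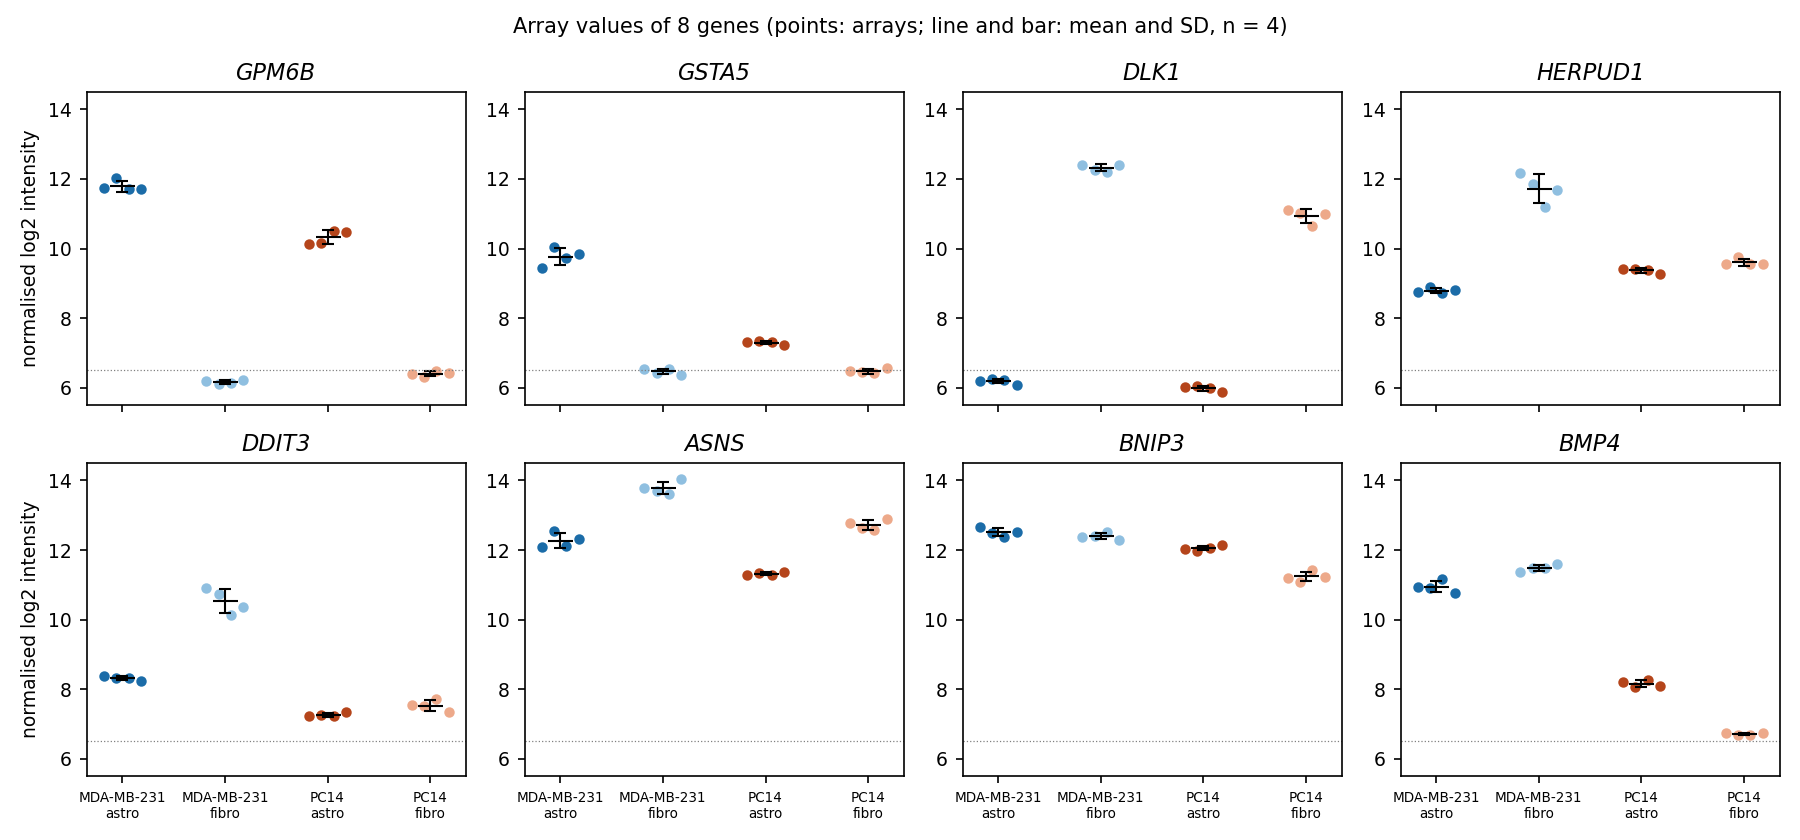
Normalised log2 intensity of 8 genes on each of the 16 arrays by group; points are arrays, and the bar gives the mean and SD of 4. The dotted line marks log2 6.5, and DLK1 lies below it beside astrocytes in both lines, at 6.19 and 5.98, against 12.32 and 10.94 beside fibroblasts.

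Genes of the unfolded protein and ATF4 responses, through which cells handle misfolded protein and amino acid shortage, fell together in MDA-MB-231. Of 37 measured members 29 fell and 1 rose, and 34 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.8e-64; adjusted p = 5.5e-04 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.38 ± 0.06 on the log2 scale, and ASNS, asparagine synthetase, fell by 1.51 ± 0.09. ATF3, a stress-induced transcription factor, fell by 0.72 ± 0.09, and GADD45A, a gene of growth arrest, fell by 0.92 ± 0.11. The member that rose was PDIA6, a protein disulphide isomerase, by 0.52 ± 0.10; it was picked out after its values were seen.

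Immediate early genes, which respond first to growth signals, also fell, 8 of 23 measured and 9 adjusted over the list alone (adjusted p = 8.6e-10). MYC fell by 0.80 ± 0.08 and PHLDA1 by 0.84 ± 0.08. Of the targets of NRF2, the regulator of the antioxidant response, 7 of 20 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 1.1e-05). NQO1, a quinone reductase, fell by 0.66 ± 0.06, the iron-binding protein gene PIR by 0.63 ± 0.07, and ABCC3, an export pump for conjugates, by 0.89 ± 0.08. Camera with an estimated correlation gave an adjusted p of 0.0288 for the immediate early list and 0.0474 for the NRF2 list. Among p53 targets 3 of 19 fell (5 adjusted over the list alone, list adjusted p = 0.0032), with the stress cytokine GDF15 falling by 0.68 ± 0.09. Some members are also in the unfolded protein and ATF4 list, namely GADD45A and SESN2 (p53), ATF3 (immediate early) and SLC7A11 (NRF2). These lists were not tested without the shared genes, so their falls are not separate evidence. Of the cholesterol and fatty acid synthesis genes 3 of 27 fell (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.00295), among them the desaturase gene SCD by 0.59 ± 0.07.

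Of 43 interferon-stimulated genes 10 fell and 1 rose (14 and 3 adjusted over the list alone; adjusted p = 4.7e-05): the antiviral membrane protein gene BST2 fell by 0.60 ± 0.07 and IFI35 by 0.41 ± 0.07, while IFIH1, a sensor of double-stranded RNA, rose by 1.27 ± 0.07. Of 16 antigen presentation genes 4 fell (5 adjusted over the list alone; adjusted p = 9.4e-05), with B2M falling by 0.49 ± 0.09 and HLA-B by 0.47 ± 0.08. Of 13 JAK-STAT3 genes 3 fell (4 adjusted over the list alone; adjusted p = 0.00148), with SOCS1, a brake on cytokine signalling, falling by 1.04 ± 0.10 and the kinase gene PIM1 by 0.44 ± 0.08. The NF-kB and cytokine genes moved both ways, 6 of 30 down and 4 up (10 and 4 adjusted over the list alone; adjusted p = 5.4e-04, but adjusted p = 0.0838 with an estimated correlation). IL6 fell by 1.06 ± 0.10, and IL11, another cytokine that signals through gp130, rose by 0.87 ± 0.07. The interferon list passed only narrowly with an estimated correlation (adjusted p = 0.0469).

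Heat shock genes rose, 4 of 16 measured (7 rose and 1 fell adjusted over the list alone; adjusted p = 7.4e-05). DNAJB1, a co-chaperone, rose by 0.31 ± 0.07 and HSPA8, the constitutive HSP70, by 0.39 ± 0.10. Of 47 cell cycle genes 3 rose, among them cyclin A2, CCNA2, by 0.89 ± 0.08 (3 adjusted over the list alone; list adjusted p = 0.00302, but adjusted p = 0.158 with an estimated correlation). In the hypoxia and glycolysis list 9 of 34 genes fell and 1 rose (12 and 3 adjusted over the list alone; adjusted p = 0.00295, but adjusted p = 0.0789 with an estimated correlation). Its median change was 0.01 and its mean -0.15, so these differ in sign. DDIT4, STC2 and VEGFA are also in the unfolded protein and ATF4 list, and this comparison was not tested without them. P4HA2, a collagen hydroxylase, fell by 1.08 ± 0.08, while ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 1.45 ± 0.09. Of 10 endothelin and gap junction genes 2 rose (2 adjusted over the list alone; adjusted p = 0.0349, but adjusted p = 0.0838 with an estimated correlation), among them the connexin 43 gene GJA1 by 0.66 ± 0.08.

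Markers of the mouse partner cells were tested as lists too. Of 37 fibroblast markers 10 fell beside astrocytes in MDA-MB-231 and 0 rose (15 fell and 5 rose adjusted over the list alone; adjusted p = 4.8e-06). These included DCN, the collagen gene COL6A3 (by 1.37 ± 0.08), LOX, which crosslinks collagen (by 0.88 ± 0.10), and the calcium-binding protein gene S100A4 (by 0.72 ± 0.08). Of 33 astrocyte markers 5 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.889, but 3.6e-07 with fry, which does not compare a list with other genes; median -0.04 and mean 0.15, which differ in sign), with GPM6B and APOE, a lipid carrier (0.96 ± 0.08), rising and CPE, a prohormone-processing enzyme, falling by 1.09 ± 0.09. With 75th percentile scaling the calls of B2M, DNAJB1, HSPA8 and IFI35 and of the endothelin and gap junction list were lost, with adjusted p of 0.191, 0.285, 0.0837, 0.0526 and 0.0545. The HSPA8 call was also lost without MDA-MB-231 astrocyte array 4 (0.132) or fibroblast array 1 (0.136) or 2 (0.128). That list's call was lost without MDA-MB-231 astrocyte array 1 (0.0649) or 2 (0.0862) or fibroblast array 3 (0.0745) or 4 (0.059). It was also lost with the mean of all probes (0.0908), with only the arrays compared (0.0536) and with dim features left out (0.107). With only the arrays compared HSPA8 was lost too (0.0532).

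GSTA5, BCL2L1 and TWIST1 are genes that the same research group has reported as induced by astrocytes, possibly chosen on these arrays, so their list is not independent evidence of a direction. GSTA5 rose in both lines, 9.86-fold in MDA-MB-231 and 1.78-fold in PC14, where it stood at 7.30 ± 0.04 against 6.47 ± 0.06 (SD, n = 4; adjusted p = 1.0e-06). BCL2L1, an inhibitor of apoptosis, changed by 0.18 ± 0.07 in MDA-MB-231 (adjusted p = 0.244) and 0.04 ± 0.07 in PC14 (adjusted p = 0.928). TWIST1, a regulator of mesenchymal fate, lay near the floor in every group, at 5.94 to 6.07, so no change of it could be measured. Adjusted over the list alone, 2 of the 3 genes were higher in MDA-MB-231 and 1 in PC14. The list passed in MDA-MB-231 (adjusted p = 2.3e-05) and in PC14 (adjusted p = 0.00321, but adjusted p = 0.0967 with an estimated correlation).

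The second comparison put the same question to PC14. GPM6B was 15.2-fold higher beside astrocytes, at 10.32 ± 0.20 against 6.40 ± 0.07 (SD, n = 4; log2 change 3.92 ± 0.08). NREP was 8.87-fold higher, and APOBEC3F, an antiviral cytidine deaminase, was 6.93-fold higher, at 9.50 ± 0.11 against 6.71 ± 0.05 (adjusted p = 2.7e-18). EFNB2 was 6.33-fold higher, MMP10, a matrix metalloproteinase, 6.02-fold, RENBP 4.62-fold, TCF4 4.14-fold and IFIH1 4.10-fold. DLK1 was 31.1-fold lower, at 5.98 ± 0.07 against 10.94 ± 0.21, a log2 change of -4.96 ± 0.08. MBD3L3, of the methyl-binding domain family, was 4.61-fold lower, at 6.66 ± 0.10 against 8.86 ± 0.12, DCN 3.92-fold, and FFAR4, a receptor for long-chain fatty acids, 3.70-fold. RAB42 was 3.49-fold lower, MEIS1 3.24-fold, the noncoding RNA gene RN7SK, which restrains transcription elongation, 2.84-fold, and the homeobox gene ZFHX4 2.82-fold.

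In PC14 limma called 635 genes, 321 higher and 314 lower beside astrocytes, with a median absolute log2 change of 0.37. Of these, 19 were over 2-fold higher and 25 over 2-fold lower, and the groups did not overlap for 546. The count depended on single arrays: it was 287 without astrocyte array 3, 376 without astrocyte array 4, 355, 308 and 372 without fibroblast arrays 1, 2 and 4, 340 without all arrays numbered 4, and 1303 without fibroblast array 3. With the replicate number as a block it was 2089, 1263 higher and 826 lower, and with 75th percentile scaling 310, 209 higher and 101 lower.

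Hypoxia and glycolysis genes rose in PC14, 9 of 34 measured with 1 falling (15 and 2 adjusted over the list alone; adjusted p = 4.0e-11). BNIP3, a mitochondrial protein gene induced by low oxygen, rose by 0.81 ± 0.07, ANGPTL4 by 0.98 ± 0.09 and PFKFB4, a regulator of glycolysis, by 0.65 ± 0.08, while LOX fell by 1.14 ± 0.10. Of 25 TGF-beta and YAP genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 2.1e-04). The growth factor gene BMP4 rose by 1.46 ± 0.07, from 6.70 ± 0.03 to 8.15 ± 0.09, TGFB2 by 1.98 ± 0.12 and ID1, a target of BMP signalling, by 0.38 ± 0.08. Of 47 cell cycle genes 4 rose, and 14 adjusted over the list alone (adjusted p = 8.1e-08). Among them CCNE2, cyclin E2, rose by 0.53 ± 0.10 and HMMR, a protein of the mitotic spindle, by 0.50 ± 0.11. The cell cycle list had an adjusted p of 0.0367 with an estimated correlation.

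The unfolded protein and ATF4 genes were lower in PC14, 8 of 37 down and 1 up (18 and 3 adjusted over the list alone; adjusted p = 9.5e-09, but adjusted p = 0.11 with an estimated correlation). ASNS fell by 1.40 ± 0.09, PCK2, the mitochondrial PEP carboxykinase, by 0.97 ± 0.14, PSPH, which completes serine synthesis, by 0.79 ± 0.13 and the stress gene NUPR1 by 0.61 ± 0.07. HSPA5 was the member that rose, by 0.29 ± 0.06. Of 20 NRF2 targets 4 fell (7 adjusted over the list alone; adjusted p = 2.4e-06, but adjusted p = 0.0564 with an estimated correlation), among them the aldo-keto reductase genes AKR1C3 by 1.14 ± 0.08 and AKR1B10 by 0.51 ± 0.08. Of 17 Notch pathway genes 2 fell, HEY1 by 0.34 ± 0.06 and HES4 by 0.31 ± 0.08 (4 adjusted over the list alone; adjusted p = 2.1e-04). Of 23 immediate early genes 2 fell (5 adjusted over the list alone; adjusted p = 3.7e-04, but adjusted p = 0.206 with an estimated correlation). CDKN1A, which arrests the cell cycle, fell by 0.97 ± 0.10, and IFITM1, an antiviral membrane protein gene, by 1.31 ± 0.18. The Notch list passed only narrowly with an estimated correlation (adjusted p = 0.0481).

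Partner cell markers were tested in PC14 too. Of 37 fibroblast markers 10 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 4.0e-11), with TWIST2, a mesenchymal transcription factor, falling by 1.31 ± 0.13 and COL6A3 by 0.66 ± 0.08. Of 33 astrocyte markers 4 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.0168): GPM6B, APOE by 1.23 ± 0.08, the receptor phosphatase gene PTPRZ1 by 1.07 ± 0.06 and the matrix protein gene SPARCL1 by 0.86 ± 0.07. The median of that list was -0.02 and its mean 0.20, so these differ in sign, and its call was lost without astrocyte array 2 (adjusted p = 0.0631). Its adjusted p was 0.0481 with an estimated correlation. With 75th percentile scaling the calls of the NRF2, unfolded protein, immediate early and Notch lists were lost, with adjusted p of 0.0924, 0.106, 0.411 and 0.311. That scaling also ended the calls of HSPA5 (0.0573), HEY1 (0.3) and HES4 (0.49). Those of CCNE2 (0.0577), ID1 (0.0615), HMMR (0.12) and HES4 (0.18) ended without the arrays numbered 4. Among single PC14 arrays, leaving out astrocyte array 3 or fibroblast array 1, 2 or 4 ended the calls of HSPA5 (0.0866, 0.0653, 0.0569 and 0.0545), HMMR (0.0892, 0.0511, 0.0757 and 0.061) and HES4 (0.236, 0.0947, 0.191 and 0.133). Leaving out astrocyte array 4 ended those of HMMR (0.0538) and HES4 (0.0889), and HES4 was also lost without PC14 astrocyte array 1 (0.0673) or MDA-MB-231 astrocyte array 3 (0.0562). The mean of all probes ended the calls of ID1 (0.102) and CCNE2 (0.0745), the variance trend those of HSPA5 (0.0634) and HES4 (0.0674), and only the arrays compared that of HES4 (0.0613). With fry the immediate early list did not pass (0.0634).

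The third comparison set the 2 lines side by side. In the same direction in both lines were 211 genes, 84 higher and 127 lower beside astrocytes, where independent lists of those sizes would share 9.17 and 11.6. GPM6B, EFNB2, TCF4, NREP, RENBP, APOBEC3F, MMP10 and IFIH1 were the genes with the largest rises shared by both. DLK1, DCN, FFAR4, RAB42, MEIS1, ZFHX4, STEAP1 and ASNS led the shared falls; STEAP1, a metalloreductase, was 4.38-fold and 2.74-fold lower on the brightest of its 4 probes, while another, with a mean of 7.60, changed by 0.27 (adjusted p = 0.158) and 0.19 (adjusted p = 0.442). Likewise a further APOBEC3F probe, with a mean of 7.18, changed by -0.25 (adjusted p = 0.118) and -0.17 (adjusted p = 0.423). Another 16 genes passed in opposite directions. Across the 1640 genes called in either line 71% had the same sign, and the changes correlated with r = 0.59, against r = 0.43 across 13848 genes brighter than the median feature; genes are not independent replicates. The 2 comparisons share no arrays, but they share the estimate of each gene's spread, so their lists are not fully independent. The expected counts also run over all 18773 named genes, those near the floor included. The shared count was 437 with the replicate number as a block, 107 with 75th percentile scaling (55 higher and 52 lower), 137 without the arrays numbered 4, 136 without PC14 astrocyte array 3 and 137 without PC14 fibroblast array 1.

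**Figure D2:**
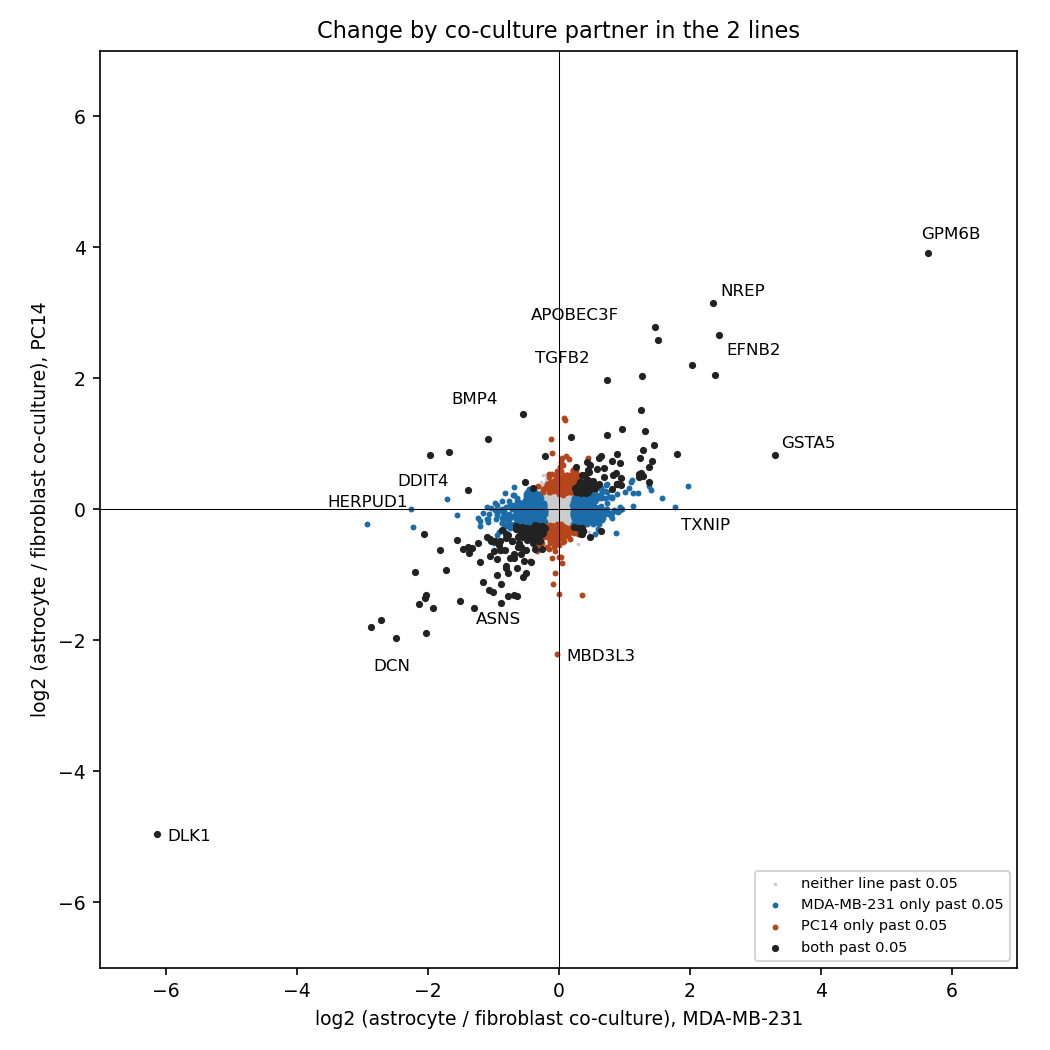
Log2 change of astrocyte over fibroblast co-culture for each named gene in MDA-MB-231 (horizontal) and PC14 (vertical); black points passed an adjusted p of 0.05 in both lines, blue points in MDA-MB-231 alone, red-brown points in PC14 alone and grey points in neither. GPM6B lies at 5.63 and 3.92 and DLK1 at -6.13 and -4.96, while HERPUD1 and DDIT4 lie near the horizontal axis, at -0.22 and 0.00 in PC14.

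The difference of the partner effect between the lines was tested itself, as the PC14 change minus the MDA-MB-231 change. FILIP1L, of the filamin-interacting family, fell 3.93-fold in MDA-MB-231 and rose 1.78-fold in PC14, a difference of 2.81 ± 0.19. FLRT3, a cell adhesion protein gene, fell 3.20-fold and rose 1.82-fold, and TMEM47, a junction protein gene, fell 2.12-fold and rose 2.09-fold. HERPUD1 and DDIT4 fell in MDA-MB-231, with differences of 2.71 ± 0.17 and 2.26 ± 0.17, and DDIT4 changed by 0.00 ± 0.12 in PC14 (adjusted p = 1). HERPUD1 changed there by -0.22 ± 0.12 (adjusted p = 0.499), an error pooled over all 4 groups. With the replicate number as a block its adjusted p was 0.166, and with the PC14 arrays alone 0.104. Its PC14 values did not overlap between the partners, so a small fall is not excluded. On the other side, the rise of GSTA5 was smaller in PC14 by 2.47 ± 0.12, and MBD3L3 fell in PC14 but not measurably in MDA-MB-231, where it lay near the floor (difference -2.17 ± 0.10). TXNIP, an inhibitor of thioredoxin, rose 3.42-fold in MDA-MB-231 and lay near the floor in PC14, at 6.15 and 6.12 (difference -1.74 ± 0.15). GPM6B and TWIST2 differed by -1.71 ± 0.12 and -1.66 ± 0.19. Beside fibroblasts GSTA5 and GPM6B lay near the floor in both lines, so their differences reflect mainly the levels beside astrocytes. In all 529 genes differed, 263 with a more positive change in PC14 and 266 with a more negative one, and 1454 with the replicate number as a block or 205 (129 and 76) with 75th percentile scaling.

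In the unfolded protein and ATF4 list 12 of 37 members were more positive in PC14 and none more negative (23 and 2 adjusted over the list alone; adjusted p = 8.8e-26, and 0.0157 with an estimated correlation). HSPA5 differed by 1.66 ± 0.09 and DDIT3 by 1.95 ± 0.16, whereas ASNS differed by 0.11 ± 0.13 (adjusted p = 0.865). In the hypoxia and glycolysis list 10 of 34 were more positive (15 more positive and 1 more negative adjusted over the list alone; adjusted p = 1.1e-15, and 0.00121 with an estimated correlation). P4HA2 differed by 0.93 ± 0.11, BNIP3 by 0.70 ± 0.10, PFKFB4 by 0.63 ± 0.11 and STC2, a secreted glycoprotein gene, by 0.43 ± 0.09. Of 25 TGF-beta and YAP genes 5 were more positive and 2 more negative (6 and 4 adjusted over the list alone; adjusted p = 0.0318, but adjusted p = 0.108 with an estimated correlation); BMP4 differed by 1.99 ± 0.10. Interferon-stimulated genes had 2 of 43 more positive (4 more positive and 1 more negative adjusted over the list alone; adjusted p = 0.0104, but adjusted p = 0.283 with an estimated correlation). Immediate early genes had 2 of 23, MYC by 0.83 ± 0.11 and PHLDA1 by 0.79 ± 0.12 (3 adjusted over the list alone; adjusted p = 0.0142, but adjusted p = 0.383 with an estimated correlation). With 75th percentile scaling the calls of BNIP3 (0.12) and PFKFB4 (0.0641) were lost. The reported survival genes had 1 of 3 more negative, GSTA5 (1 adjusted over the list alone; adjusted p = 0.00207, but adjusted p = 0.108 with an estimated correlation). Without single arrays the highest adjusted p was 0.0938 for the TGF-beta and YAP list and 0.0974 for the immediate early list, without PC14 astrocyte array 2 and MDA-MB-231 fibroblast array 1. The interferon list was lost without MDA-MB-231 astrocyte array 4 (0.0526). Cyclic loess ended the interferon (0.229) and TGF-beta and YAP (0.129) calls, and leaving out dim features ended those and the immediate early call (0.065, 0.149 and 0.065). With fry the interferon (0.0669) and immediate early (0.143) lists did not pass. The immediate early list was also lost without PC14 astrocyte array 2 (0.0938) or fibroblast array 3 (0.0532). The TGF-beta and YAP list was also lost without PC14 fibroblast array 3 (0.0886), MDA-MB-231 fibroblast array 1 (0.0569) or 2 (0.0606), or MDA-MB-231 astrocyte array 1 (0.0583) or 4 (0.0501).

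**Figure D3:**
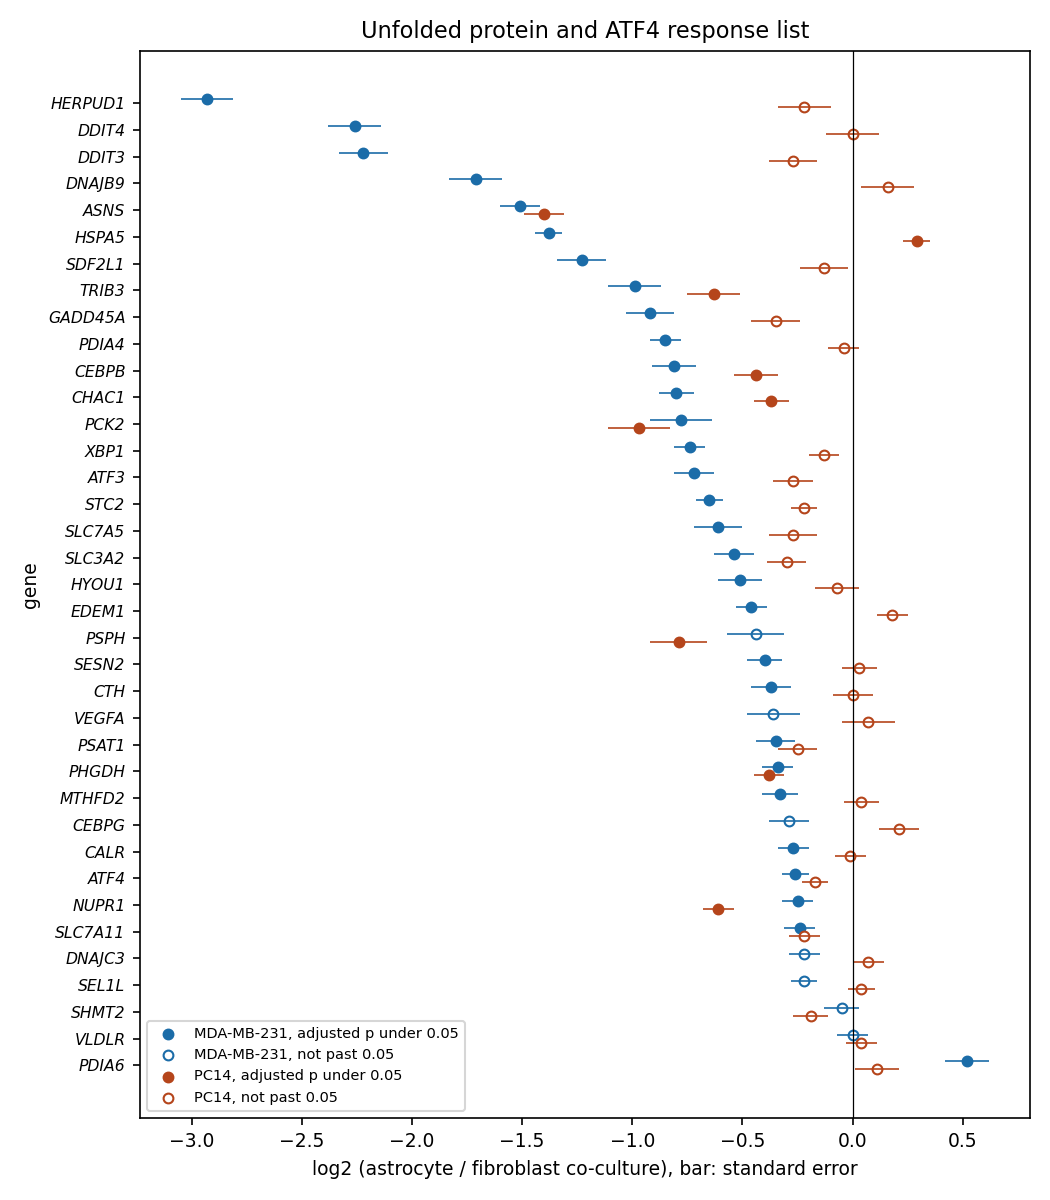
Log2 change of astrocyte over fibroblast co-culture with its standard error for the 37 genes of the unfolded protein and ATF4 list, in MDA-MB-231 (blue) and PC14 (red-brown); filled points passed an adjusted p of 0.05. HSPA5 lies at -1.38 in MDA-MB-231 and 0.29 in PC14, and ASNS at -1.51 and -1.40.

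The last comparison averaged over the partners and set PC14 against MDA-MB-231. PC14 expressed cancer-testis genes that lay at the floor in MDA-MB-231: GAGE12J was 440-fold higher (log2 change 8.78 ± 0.05), VCX 273-fold, GAGE7 205-fold and CT45A3 101-fold, and members of these families share sequence, so probes may read more than 1 copy. The imprinted noncoding RNA gene H19 was 140-fold higher, LRCH4 63.2-fold, CRIP1 59.1-fold and UCHL1, a ubiquitin hydrolase gene of neurons, 56.4-fold. Higher in MDA-MB-231 were DKK1, an inhibitor of Wnt signalling (96.7-fold; log2 change -6.60 ± 0.06), ANKRD1, a target of YAP (92.8-fold), DENND2A (75.5-fold), VAMP8, of vesicle fusion (57.4-fold), the proteoglycan gene SRGN (53.7-fold), the GTPase gene RAC2 (43.8-fold) and DECR1, of fatty acid oxidation (43.0-fold). In all limma called 9732 genes, 4924 higher and 4808 lower in PC14.

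Interferon-stimulated genes were lower in PC14, 36 of 43 with 1 higher (36 and 1 adjusted over the list alone; adjusted p = 5.3e-30); IFIH1 was 3.25-fold and BST2 2.40-fold lower. Antigen presentation genes were lower for 13 of 16 (13 adjusted over the list alone; adjusted p = 1.5e-09), with B2M 4.88-fold lower. NF-kB and cytokine genes were lower for 21 of 30 and higher for 2 (22 and 2 adjusted over the list alone; adjusted p = 4.7e-14), with IL11 23.2-fold and IL6 9.77-fold lower. TGF-beta and YAP genes were lower for 19 of 25 and higher for 3 (19 and 3 adjusted over the list alone; adjusted p = 3.2e-12), with BMP4 13.8-fold lower. NRF2 targets were higher for 14 of 20 and lower for 1 (15 and 1 adjusted over the list alone; adjusted p = 1.2e-09), with PIR 9.80-fold higher. Fibroblast markers were lower for 21 of 37 and higher for 4 (23 and 5 adjusted over the list alone; adjusted p = 2.4e-06); S100A4 was among the higher, at 32.8-fold.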

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

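The tests of other splits of the arrays, of a fixed mouse RNA profile, of the arrays numbered 4 and of the normalization of the hypoxia list, and the limit from the spread of the genes read in 1 line alone, were chosen only after the result was seen.

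The partner effect differed between the lines, by the test of the difference itself, for 53 of the 99 named genes. The differences, PC14 minus MDA-MB-231 on the log2 scale, were most positive for FILIP1L (2.81), HERPUD1 (2.71), FLRT3 (2.55), DDIT4 (2.26), TMEM47 (2.15), BMP4 (1.99), DDIT3 (1.95) and HSPA5 (1.66). They were most negative for GSTA5 (-2.47), MBD3L3 (-2.17), TXNIP (-1.74), GPM6B (-1.71), TWIST2 (-1.66) and STMN2 (-1.63). Also positive were APOBEC3F (1.32), TGFB2 (1.23), FEZ1 (1.22), PTPRZ1 (1.19), DLK1 (1.17), RAB42 (1.07), MMP10 (1.07), MEIS1 (1.02), IL6 (0.99), SPARCL1 (0.96), CPE (0.94), P4HA2 (0.93), MYC (0.83), MMP1 (0.81), NREP (0.80), PHLDA1 (0.79), IFIH1 (0.76), ZEB2 (0.72), COL6A3 (0.71) and BNIP3 (0.70). Smaller positive differences were those of STEAP1 (0.67), BST2 (0.65), PFKFB4 (0.63), DKK1 (0.62), DENND2A (0.56), SOCS1 (0.55), NQO1 (0.52), DCN (0.51), SCD (0.50), HLA-B (0.49), PIR (0.48) and STC2 (0.43). The other negative ones were AKR1C3 (-1.05), CDKN1A (-0.92), IL11 (-0.89), GJA1 (-0.73), CCNA2 (-0.66), HEY1 (-0.55) and ID1 (-0.51). Some of these rest on levels near the floor, under log2 6.5, where changes are poorly measured. DLK1, RAB42 and DCN lay there beside astrocytes in both lines, and GPM6B, GSTA5 and MMP10 beside fibroblasts in both, so their differences reflect mainly the levels on the other side. STMN2 lay there beside fibroblasts in MDA-MB-231, and IFIH1, TGFB2, PTPRZ1 and SPARCL1 beside fibroblasts in PC14. With both partners MBD3L3, PTPRZ1 and SPARCL1 lay there in MDA-MB-231, and STMN2, TXNIP, BST2, IL11, IL6, GJA1, DKK1 and DENND2A in PC14, so no change could be measured in that line. Calls of differences ended with 75th percentile scaling for DCN (0.59), ID1 (0.314), SCD (0.312), RAB42 (0.312), HEY1 (0.252), DKK1 (0.249), NQO1 (0.227), CCNA2 (0.223), SOCS1 (0.216), STEAP1 (0.199), PIR (0.141), BNIP3 (0.12), ZEB2 (0.0983), HLA-B (0.0687), DENND2A (0.0687), MMP1 (0.0663) and PFKFB4 (0.0641). They ended with cyclic loess for DCN (0.734), DENND2A (0.419), DKK1 (0.353), RAB42 (0.221), SOCS1 (0.143), ZEB2 (0.0789) and DLK1 (0.0702), and with the mean of all probes for STEAP1 (0.795), ID1 (0.328), DCN (0.168), ZEB2 (0.115) and BST2 (0.0739). The variance trend ended those of RAB42 (0.124) and ZEB2 (0.0689), and leaving out the arrays numbered 4 those of ZEB2 (0.0965) and DCN (0.0524). The calls of DCN, HLA-B, SOCS1 and ZEB2 also ended without several single arrays, with the highest adjusted p at 0.0786, 0.0852, 0.0979 and 0.118. Of the gene lists 6 differed: the unfolded protein and ATF4 list (adjusted p = 8.8e-26), hypoxia and glycolysis (1.1e-15), the reported survival genes (0.00207), interferon-stimulated (0.0104), immediate early (0.0142) and TGF-beta and YAP (0.0318). The last 4 were lost with an estimated correlation (adjusted p = 0.108, 0.283, 0.383 and 0.108).

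In 24 of 400 groups of 4 values, 1 array stood apart from its group, where 20 would be expected by chance at 1 in 20. Of these values 8 lay on arrays numbered 4, 7 on arrays numbered 2, 5 on arrays numbered 1 and 4 on arrays numbered 3. The median raw intensity of MDA-MB-231 astrocyte array 4 was 78.8. In MDA-MB-231 astrocyte co-cultures the log2 values were 12.02 for GPM6B, 8.66 for FILIP1L, 10.88 for PSPH and 5.76 for VCX on array 2, 14.32 for HSPA8 and 9.17 for TGFB2 on array 4, and 9.27 for IL6 on array 1. In MDA-MB-231 fibroblast co-cultures they were 6.33 for STMN2 on array 2, 9.42 for TXNIP, 11.04 for MYC and 8.09 for S100A4 on array 3, 6.14 for MBD3L3, 7.47 for GJA1 and 6.97 for LRCH4 on array 1, and 11.37 for SRGN on array 4. In PC14 astrocyte co-cultures they were 6.81 for MBD3L3 on array 2, 6.14 for IL6 on array 1, 8.88 for ID1 on array 3, and 7.78 for CDH2 and 14.44 for GAGE7 on array 4. In PC14 fibroblast co-cultures they were 9.74 for HERPUD1 on array 2, and 6.45 for BST2 and 13.30 for H19 on array 4.

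Over splits that ignore the replicate numbers, chance could be excluded as the source of the counts within each line and of the count between the lines. Of the 35 splits of the 8 arrays of a line, only the real split (1) reached 1232 genes in MDA-MB-231, where the highest other gave 26, and only the real split reached 635 in PC14, where the highest other gave 412. That PC14 split set astrocyte arrays 1, 3 and 4 with fibroblast array 3 against the rest. Of 100 drawn splits only the real one reached 211 for the shared genes (highest other 0) and 9732 for the lines (highest other 0). For the difference between lines the real one gave 529 and the highest other 489. The draws for this difference and for the shared genes shuffled the partners within each line, which assumes no partner effect in either line. They therefore cannot decide whether that effect differed between the lines, or whether the lines shared more genes than independent lists would. With the numbers kept as pairs, 8 splits in each line are too few for a share under 0.05; the real ones gave 1232 and 635 and the highest other 0 in both. Of the 35 splits of the 8 pair differences only the real one (1) reached 1454 genes for the difference between lines. The highest other gave 1, so chance could be excluded for this difference. Of 64 drawn swaps within pairs only the real one reached 211 shared genes, where the highest other gave 16. These swaps too assume no partner effect in either line, so they cannot decide whether the overlap exceeded that of independent lists.

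The first pattern weighed is the set of 211 genes that moved the same way in both lines. A fixed mouse RNA profile added to the arrays of each line at 1 share is argued against as the source of all 84 shared rises. Of these, 53.6% departed from the median ratio of PC14 over MDA-MB-231 increments, 0.638, by over 2 standard errors. Among the 9 named genes the ratio ran from 0.0879 for GSTA5 to 3.09 for MMP10. It was nearly equal for GPM6B (0.345), EFNB2 (0.347) and TCF4 (0.365), so such a profile stays open for these genes. It was 0.517 for IFIH1, 1.12 for RENBP, 1.78 for NREP and 2.52 for APOBEC3F. Mouse RNA read by human probes in general stays open. Of the shared genes 9.48% (20 of 211) had the lower group mean under log2 6.5 in both lines. Of the genes changed in 1 line alone 7.08% (100 of 1413) had it so in that line (exact Fisher p = 0.206). The shared genes thus met a stricter condition, so this test decides nothing. The mouse arrays were not analysed here, so a response of the human cells and RNA of the partner cannot be told apart for these genes.

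The second pattern is the fall of unfolded protein and ATF4 genes in MDA-MB-231. A smaller share of human RNA beside astrocytes is argued against as the source of this fall. On the same normalised scale, 143 genes read in MDA-MB-231 alone had a median change of 0.00 (lower end of the interval -0.06) against -0.51 for the list. Quantile normalisation can remove an even drop, so this does not show that the share stayed the same. Of the 143 genes 26 were higher and 32 lower, 40.6% called against 6.56% of all named genes, those near the floor included. Their SD was 0.38 and their interquartile range 0.42, so the list lay further off than their spread. By definition they lay under log2 6.5 in both PC14 groups, so in PC14 their probes read no large signal from either partner. Whether mouse RNA contributed to their changes in MDA-MB-231 was not tested. The arrays numbered 4 are argued against, since without them 26 of the 29 genes were still called lower. For a mouse profile that fibroblasts add in both lines, the 29 called genes had a median ratio of increments of 0.105 (interval 0.038 to 0.318) against a reference of 0.421 from DCN, RAB42 and DLK1, genes near the floor beside astrocytes. After that outcome the list was divided: the 9 endoplasmic reticulum genes had 0.038 (-0.118 to 0.0998) and the 9 amino acid genes 0.456 (0.00647 to 0.703). A reference of 3 genes is too few to fix a profile, so these ratios exclude nothing, and a mouse profile that differs between the lines was not tested. Mouse RNA stays open for the list and both its parts, and a response of the human cells to the partner stays a hypothesis.

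The third pattern is the difference between the lines in the hypoxia and glycolysis list. The between-array normalization is argued against, since the highest adjusted p over the 2 others run, 75th percentile scaling and cyclic loess, was 1.8e-15. With 75th percentile scaling further lists also passed for this difference, such as cell cycle (camera adjusted p = 9.0e-06) and cholesterol (1.5e-04). BNIP3 and PFKFB4 lost their calls under it, so the pass with that scaling alone carries little weight. Genes shared with the unfolded protein list are argued against as the whole cause, since without those 3 genes the adjusted p was 1.3e-11 (0.00467 with an estimated correlation). A larger share of human RNA beside astrocytes in PC14 stays open. The 130 genes read in PC14 alone had a median change of -0.10 (upper end of the interval -0.06) against 0.16 for the list. However, their interquartile range of 0.26 (SD 0.19) was as wide as that gap. Of them 6 were higher and 9 lower, 11.5% called against 3.38% of all named genes. Mouse RNA was not tested for this list and stays open, as does a line-specific response to the partner.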

How the results depend on the processing

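The alternatives that left out dim features or the 4 arrays numbered 4 were chosen only after the data had been seen. So were those that shared the block between lines or that adjusted over named genes alone. For the gene lists, the alternatives fixed beforehand were cyclic loess, the authors' processed values, the block within each line, the estimated correlation and fry. Every other alternative given for the lists was not fixed beforehand for them. Not run were a detection p filter and a slide block, since the files give neither, and no filter on detection and normexp with offset 50, which were already in use.

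The counts moved by more than 1.5 times as follows, and the causes were not tested. With 75th percentile scaling they were 591 in MDA-MB-231, 310 in PC14, 205 for the difference and 107 shared. With the replicate block within each line they were 1918, 2089, 1454 and 437, and with the block shared by both lines 1853, 1966, 1348 and 419. Without the arrays numbered 4, PC14 gave 340 and the shared genes 137, with fewer arrays fitted. Adjusted over named genes alone, PC14 gave 1053. Leaving out each array in turn moved only the PC14 count (6 arrays) and the shared count (2 arrays) by more than 1.5 times. The ranges were 946 to 1282 in MDA-MB-231, 287 to 1303 in PC14, 353 to 705 for the difference, 136 to 250 shared and 9468 to 9756 for the lines. The lowest PC14 and shared counts came without PC14 astrocyte array 3 and the highest PC14 count without PC14 fibroblast array 3.

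Of the lists past the threshold, an estimated correlation left 6 of 10 in PC14 and 2 of 6 for the difference. The replicate block within each line narrowly added the p53 (adjusted p = 0.0489) and heat shock (0.0496) lists in PC14. It also narrowly added the endothelin and gap junction list for the difference (0.05 after rounding). For the difference, 75th percentile scaling gave 15 lists and leaving out dim features 2. The cholesterol list reversed in PC14 with 75th percentile scaling (adjusted p = 0.0354), and the protease list reversed there with fry (0.00246), which does not compare a list with other genes.

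Of the single-gene results, 75th percentile scaling ended 83 calls, leaving out the arrays numbered 4 ended 33, cyclic loess 21, the mean of all probes 20 and the variance trend 19, while the replicate block within each line ended 0 and added 95. With 75th percentile scaling the median change of named genes lay between -0.06 and 0.01 over the comparisons. Signal over background limits genes near the floor, whose folds can be understated.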

Other observations

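The test of the endoplasmic reticulum genes against the amino acid genes was chosen only after the result was seen.

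Further genes moved with the partner. In MDA-MB-231 CDH2, the neuronal cadherin, rose by 1.25 ± 0.13, and ID1 rose by 0.89 ± 0.08. ZEB2, a repressor of epithelial genes, fell there by 1.32 ± 0.13 and MMP1, a collagenase, by 0.96 ± 0.10 on the log2 scale. ZEB2 changed in PC14 by -0.59 and ID1 by 0.38. CDH2 was higher beside astrocytes there too, without overlap of the array values, while the MMP1 values overlapped. In both lines IFI35 fell by 0.41 ± 0.07, and SOCS1 fell by 1.04 ± 0.10 and 0.49 ± 0.10; with 75th percentile scaling the calls of IFI35 in both lines (0.0526 and 0.171) and of SOCS1 in PC14 (0.139) were lost. Between the lines, Notch pathway genes were higher in PC14 for 11 of 17 and lower for 1 (11 and 1 adjusted over the list alone; adjusted p = 2.4e-06), with HEY1 3.44-fold higher. Cholesterol genes were higher for 19 of 27 and lower for 6 (19 and 6 adjusted over the list alone; adjusted p = 1.7e-04), with SCD 3.43-fold higher. Unfolded protein and ATF4 genes were lower for 28 of 37 and higher for 6 (28 and 6 adjusted over the list alone; adjusted p = 3.3e-08, but adjusted p = 0.0958 with an estimated correlation), with ATF3 5.92-fold lower.

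Several lists did not pass for the partner in either line. In MDA-MB-231 and PC14 the adjusted p was 0.796 and 0.17 for the anti-apoptotic genes, 0.889 and 0.992 for the pro-apoptotic genes, 0.823 and 0.881 for the glutathione S-transferases, 0.478 and 0.694 for the drug transporters, 0.796 and 0.387 for the EMT regulators and 0.856 and 0.881 for the epithelial genes. It was 0.953 and 0.17 for the metallothioneins, 0.372 and 0.881 for the proteases, 0.849 and 0.862 for the serpins, 0.849 and 0.88 for the neural genes, 0.849 and 0.873 for the ribosomal proteins and 0.52 and 0.45 for oxidative phosphorylation. For the markers of microglia it was 0.178 and 0.438, of oligodendrocytes 0.771 and 0.881, and of endothelial cells 0.21 and 0.929. With 75th percentile scaling the anti-apoptotic genes passed in PC14 (0.0011), the ribosomal proteins in MDA-MB-231 (0.00616) and oxidative phosphorylation in both lines (0.0336 and 0.0134), and with cyclic loess the ribosomal proteins passed in PC14 (0.0151). With fry, which does not compare a list with other genes, the glutathione S-transferases (0.00303), drug transporters (0.0237) and microglia markers (0.00279) passed in MDA-MB-231, and the anti-apoptotic genes and metallothioneins (0.0335 each) and, with the opposite sign to camera, the proteases (0.00246) in PC14.

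A hypothesis formed on these data is that the endoplasmic reticulum genes of the unfolded protein list differ more between the lines than its amino acid genes. The 12 endoplasmic reticulum genes changed by -0.83 on average in MDA-MB-231 (SD 0.89) and 0.02 in PC14 (SD 0.15), and the 11 amino acid genes by -0.50 (SD 0.38) and -0.43 (SD 0.44). The difference between the parts was 0.78 on the log2 scale (two-sided permutation p = 0.00381 across genes, which are not independent replicates). The separation may reflect a line-specific stress response or mouse RNA, which stays open for both parts, and it was found and tested on the same data.

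Another hypothesis was that less glucose beside fibroblasts could lie behind the higher TXNIP and lower ATF4 targets in MDA-MB-231. ARRDC4, which responds to glucose like TXNIP, changed by 0.01 (adjusted p = 0.979), but its group means were at most 6.07, near the floor, so the test decides nothing.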
